A study of Homo sapiens with 3 samples.

How the data were processed

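Total RNA of 3 cultures labelled as biological replicates was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The array model, the definition that assigns probes to genes, and the genome build are not given in the sources used here. The authors deposited 1 table with a value for each gene and array. Per the submitters' processing notes, the values were made with RMA and the affy package. The table does not name its scale. The deposited values were read as log2, the scale on which the authors' method, RMA, gives its output, and the range of the values does not contradict this. Every fold stated rests on that reading. RMA corrects background, normalises the arrays to a common distribution and summarises the probes of a gene into 1 value on the log2 scale. The sorted values of the 3 columns differed by 0.021 log2 units in the median and by at most 0.116, so the columns were close to, but not exactly at, a common distribution. RMA pulls the arrays towards each other, so an overall change in RNA content between cultures cannot be seen in such values, and differences near the lower end are compressed.

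All 24916 row identifiers had the form of an Ensembl gene identifier, with 0 repeated identifiers, 0 control probe set rows and 0 genes with the same value on all 3 arrays. The reference gene table used here held 59792 genes and an Ensembl identifier for 0 of them, so 0 of the rows were matched to a symbol. Fixed lists of genes (RAS family and pathway genes, epithelial, mesenchymal, luminal and basal genes, proliferation, stress and interferon genes, and markers of other cell types) were written before the data were examined, together with a background limit from olfactory receptor genes. None of these was used, because they need gene symbols. The tests of whether lists were above background or shifted between arrays were therefore not run, and the level of RRAS2 was not computed. The values of array control probe sets could not be given, because the rows held 0 of them. The substitute limit, stated before the data were examined for the case without gene names, was each array's median over all genes. The planned rule for named genes also needs symbols. In its place the 2 brighter genes with the largest range whose farthest array was higher, and the 2 whose farthest array was lower, are given by identifier, a choice made after the values were seen.

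From the deposited values, the SD and range over the 3 arrays were computed for each gene, and for each of the 3 pairs of arrays Pearson's and Spearman's correlation across genes and the median absolute difference. The array farthest from the middle of the 3 values was recorded for each gene. For the closing section, the distance of array 3 from array 1 was divided by that of array 2 from array 1. The calculation was tested on simulated data for 24916 genes on 3 arrays. It gave a ratio of 1.59 where array 3 had been simulated with 2 times the spread of each other array, for which 1.58 was the true value, and 0.998 where all arrays had been simulated alike. All 200 genes shifted by 2 log2 units on array 3 were found with a range over 1 unit, with 0 others. The simulated noise was alike for all genes and small beside the shift. This result checks the counting and not how the count behaves in the real data. Arrays 1 and 2 were simulated with equal spread. The test therefore does not show that the ratio measures the spread of array 3 in the real data. No test of significance was made, because the samples form 1 group without control arrays. Depth is not defined for array signals, and n = 3 limits the precision.

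The alternatives tried were quantile normalisation, centring each array on its median, cyclic loess normalisation, all genes in place of the brighter genes, at least 2 of 3 arrays in place of all 3, the array's mean as the limit, and leaving out each replicate in turn. Cyclic loess and the array mean were added after the data were seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.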

Results

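Total RNA from MDA-MB-231 cells with a silenced RRAS2 gene was profiled on Affymetrix expression arrays. MDA-MB-231 is an established human breast cancer line that is widely used as a model of triple-negative, mesenchymal-like disease, and the derivative used here is named Luc in the labels. RRAS2 encodes R-Ras2 (also called TC21), a small GTPase of the RAS family. The cells were a pool transduced with a lentivirus that encodes a short hairpin RNA against RRAS2, and they were growing exponentially when RNA was taken. The 3 arrays form 1 group, and their titles carry the mark p1, read here as pool 1. The labels call them biological replicates 1 to 3. The spread between these arrays does not cover differences between transduced pools. The series design also names cells with a control hairpin. Their arrays were not analysed here, so the effect of RRAS2 loss on any gene was not computed, and the values below describe the knockdown cells alone.

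Each array gave an expression value for 24916 human genes, named by Ensembl gene identifiers. The values were read as log2, the usual scale of RMA, which the table itself does not state, and the folds below rest on that reading. No gene symbol was paired with these identifiers in the sources used here. For this reason the level of RRAS2 itself, which would have checked the knockdown, is not given, and no gene, pathway or marker group is named below. Values were on closely similar scales. The median level was 6.84 in replicate 1, 6.81 in replicate 2 and 6.80 in replicate 3. The lowest values were 3.10, 3.15 and 3.15, and the highest were 14.26, 14.29 and 14.34, in the same order. The number of arrays limits the precision of every level.

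The set of brighter genes was largely shared by the 3 replicates. Of the 24916 genes, 12111 (48.6%) lay above the array's own median on all 3 arrays, 12106 lay at or below it on all 3, and 699 changed side between arrays. The median is a dividing line between brighter and dimmer signals and not a measured background, so it places close to 50% of genes above it by construction, and a gene below it is not shown to be silent. In what follows, brighter genes are the 12111 above the median on all 3 arrays.

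The replicates were close to one another for most genes. Across the 12111 brighter genes, the median SD over the 3 arrays was 0.087 log2 units, and 95% of genes had an SD of at most 0.226. The range from the lowest to the highest array was at most 0.5 log2 units, a 1.41-fold difference, for 97.2% of the brighter genes. Only 335 brighter genes ranged over more than 0.5 units, and 14 over more than 1 unit, which is 2-fold. With 1 array left out, the count over 1 unit was 10 without replicate 1, 4 without replicate 2 and 5 without replicate 3. The median SD was then 0.091, 0.075 and 0.053, in the same order. Fewer arrays tend to give smaller counts and SDs by construction, so these values compare only with each other. They follow from the differences within the remaining pair of arrays. When dimmer genes were included, 72 of the 24916 genes ranged over more than 1 unit.

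Replicates 1 and 2 were the closest pair, and replicate 3 lay farther away among brighter genes. Over the 12111 brighter genes, Pearson's correlation across genes was 0.996 for replicates 1 and 2, 0.993 for replicates 1 and 3, and 0.991 for replicates 2 and 3. Genes are not independent replicates, so these coefficients describe the arrays and carry no test. Levels differ far more between genes than between arrays, so high coefficients are largely set by the differences between genes. The median absolute difference was 0.074 log2 units for replicates 1 and 2, 0.107 for replicates 1 and 3, and 0.129 for replicates 2 and 3. Replicate 3 was the array farthest from the middle value for 6051 brighter genes (49.96%), replicate 2 for 3622 (29.9%) and replicate 1 for 2438 (20.1%). Arrays of equal spread would each take 33.3%. Among the 12106 dimmer genes the shares were 33.5% for replicate 3, 32.8% for replicate 2 and 33.7% for replicate 1. Among the 335 brighter genes with a range over 0.5 units, replicate 3 was farthest for 253 (75.5%), higher in 93 and lower in 160. With 3 arrays of a single group, no test of a difference between arrays was possible.

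**Figure D1:**
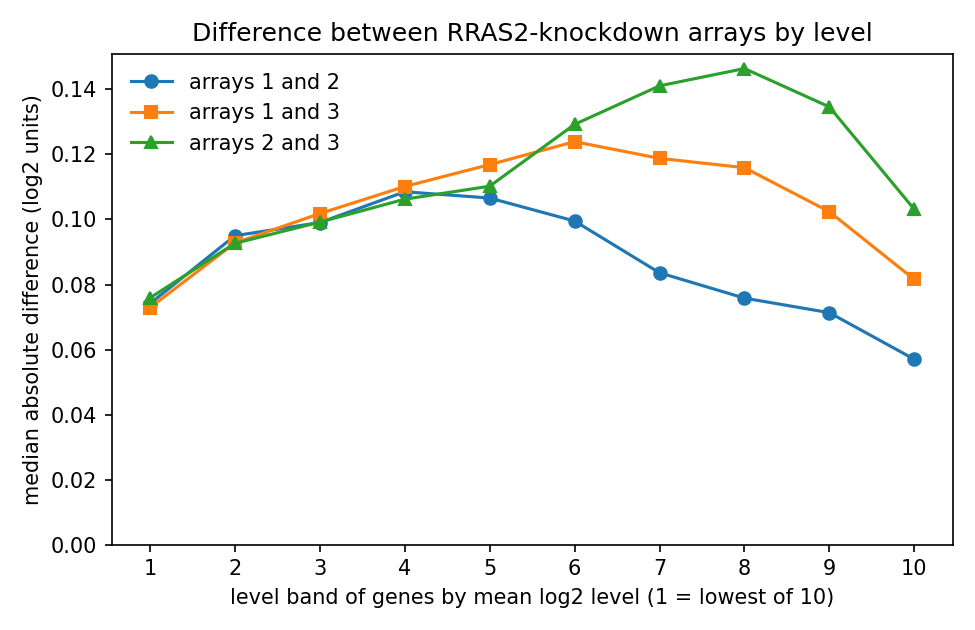
Median absolute difference in log2 level for each pair of RRAS2-knockdown arrays, by level band, where the 24916 genes were ordered by mean level and cut into 10 bands of equal size (1 is the lowest). The 3 pairs lie together in the lowest 4 bands, and in band 8 they part to 0.076 for arrays 1 and 2, 0.116 for arrays 1 and 3 and 0.146 for arrays 2 and 3.

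Few genes differed widely between replicates, and the array that stood apart was not the same for each. The 14 brighter genes with a range over 1 unit had replicate 3 as the farthest array in 8 cases, replicate 2 in 5 and replicate 1 in 1. The examples given here were chosen after the values were seen, as the largest ranges with the odd array higher and with the odd array lower. ENSG00000211459 was at 11.51 in replicate 1 against 13.46 in replicate 2 and 13.39 in replicate 3, a 3.86-fold range and a mean of 12.78 ± 1.11 (SD, n = 3). ENSG00000188015 was lowest in replicate 3 at 8.13, against 9.06 in replicate 1 and 9.22 in replicate 2 (mean 8.81 ± 0.59, SD, n = 3). Replicate 2 was the highest for ENSG00000242503, at 9.54 against 8.19 in replicate 1 and 8.39 in replicate 3 (mean 8.71 ± 0.73, SD, n = 3). It was also the highest for ENSG00000244469, at 9.14 against 8.05 in replicate 1 and 7.78 in replicate 3 (mean 8.32 ± 0.72, SD, n = 3). Array signals of different genes depend on their own probes, so the levels of these genes are not ranked against each other.

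**Figure D2:**
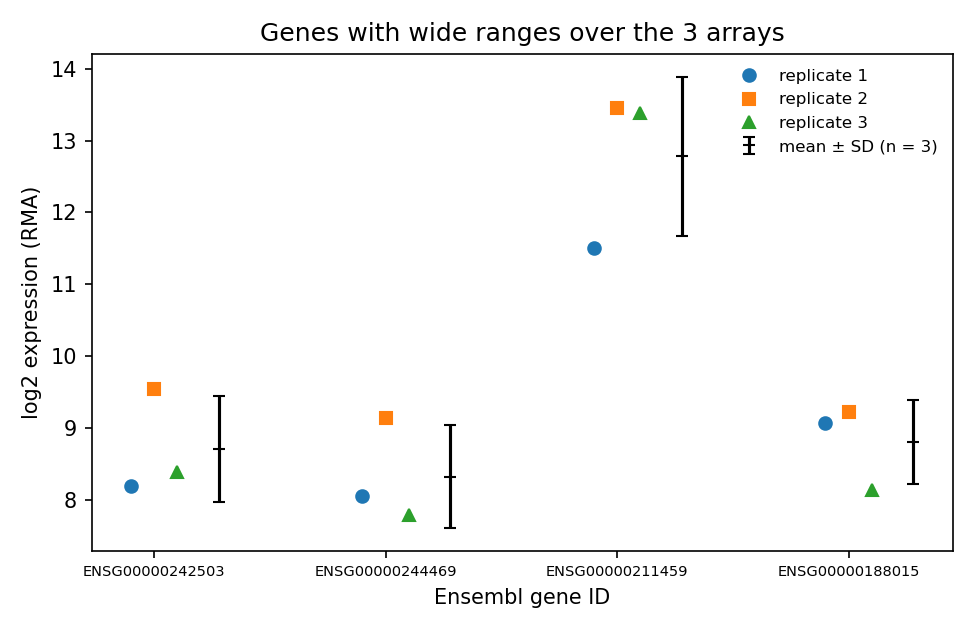
Log2 expression (RMA) of the genes named by identifier in each of the 3 RRAS2-knockdown arrays, with the mean and SD (n = 3) as a black bar beside the points. The widest range is that of ENSG00000211459, from 11.51 in replicate 1 to 13.46 in replicate 2.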

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

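The count of genes above the median on all 3 arrays stayed within 1.5 times its value of 12111 under every setting run. It went from 11161 with the array's mean as the limit to 12453 with at least 2 of 3 arrays. Each array has 12458 genes above its own median by construction, so between similar arrays this count could change little. The normalisation settings were not run for it. The median SD of brighter genes was 0.087 as deposited and 0.090 with arrays centred on their medians. With 1 array left out it was 0.091 without replicate 1, 0.075 without replicate 2 and 0.053 without replicate 3. The 14 brighter genes with a range over 1 log2 unit became 72 with all genes included, and 4 (without replicate 2) to 10 (without replicate 1) with 1 array left out. Fewer arrays give a smaller range, and tend to give a smaller median SD, by construction. The values with 1 array left out therefore compare only with each other. They follow from the differences within the remaining pair of arrays, so they restate the pair differences given above and are no separate check. Quantile and cyclic loess normalisation gave 15 genes each, and all 14 were among them. Settings that need gene symbols were not run. These were the limits from olfactory receptor, taste receptor, keratin-associated protein and defensin genes, the level of RRAS2 and the list tests. The rules for several probe sets of a gene had no use, with 0 repeated identifiers. The array control probe sets had 0 rows. No paired analysis was possible because the samples form 1 group. Signal over background could not be computed from these summarised values.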

Other observations

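The pattern weighed here was noticed in these data, and all of its tests were chosen after it was seen. Genes with a mean level above the median of all genes differed more from array 1 in array 3 than in array 2. The ratio of the median absolute differences was 1.44, and 1.01 among the genes below that median. Among the upper genes the difference between arrays 2 and 3 was 1.73 times that between arrays 1 and 2. The differences were 0.076 for arrays 1 and 2, 0.108 for arrays 1 and 3 and 0.130 for arrays 2 and 3. A level-dependent trend left by the normalisation is argued against as the whole cause, since the ratio from array 1 was 1.42 after cyclic loess. It was 1.42 after quantile normalisation and 1.39 with arrays centred on their medians, but these 2 values do not bear on such a trend. Centring moves all genes of an array alike, and the columns were already close to a common distribution. A few distant genes are argued against as the source, since they cannot move a ratio of medians. The ratio from array 1 was 1.42, 1.53, 1.44 and 1.43 in bands 7 to 10 of mean level. Array 3 was also the farthest array for 6051 (49.96%) of the 12111 brighter genes. From root mean squares the ratio was 1.36. Without the 10% of genes with the largest range it was 1.27, between the bounds of 1.1 and 1.3 set for that test. That trim cannot decide the question, because array 3 often sets the range and its removal lowers the ratio by construction. With arrays 1 and 2 alike, independent noise added to array 3 alone would leave array 3 equally far from both. Among the upper genes the differences were 0.108 from array 1 and 0.130 from array 2. The order was the same in each of bands 7 to 10. These values argue against such noise as the whole cause. A difference in the RNA preparation or culture behind array 3 may account for the pattern. It cannot be told apart from noise in hybridisation or scanning that is not confined to array 3, because there were 0 further arrays of the same RNA. No biological explanation was tested because the design gives these arrays 1 group.

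The spread between replicates differed with the number in the Ensembl identifier. When genes were cut into 10 equal bands of mean level, those numbered 200000 or higher had a larger median SD than genes of lower numbers (below 100000, and from 100000 up to 200000) in 10 of the 10 bands. In band 3 the median SD was 0.108 over 829 genes numbered 200000 or higher, 0.080 over 1517 of the middle range and 0.071 over 145 of the first. In band 8 it was 0.111 over 224 genes, 0.094 over 1903 and 0.089 over 365, in the same order. The gap was smallest in band 1, at 0.065 over 1876 genes against 0.062 over 595 of the middle range and 0.049 over 21 of the first. Levels inside a band were not matched between the number ranges. The genes have different probes, and the difference in spread was not tested as a difference in expression.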
